A study of Mus musculus with 3 samples.

How the data were processed

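Type 2 innate lymphoid cells (ILC2s), lymphocytes without rearranged antigen receptors that make type 2 cytokines in barrier tissues, were sorted from the lungs of wild-type mice given the alarmin IL-33 in vivo, per the labels. The labels' protocols describe enzymatic digestion of fresh lung, antibody staining, sorting by flow cytometry, phenol and chloroform extraction of RNA and a fragmented-mRNA library that was amplified and circularised. The antibodies and gates are not given in the sources used here. The 3 libraries carry the same labels and form 1 group, numbered 1 to 3 as in their titles. No untreated or other control library was analysed here, so no effect of IL-33 could be measured, and no test between groups was made. Nothing in the labels says whether the libraries came from separate animals, so the spread between them may be technical.

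The deposited table gives 4 quantities per gene and library, with Entrez gene IDs and symbols. The submitters' processing notes name Bowtie2, RSEM 1.3.1 and the genome build GRCm38.p6, without their order or settings. The gene annotation is not given in the sources used here. The deposited expected counts are not all whole numbers, as estimates that divide reads among matching genes are. Per the file headers, the authors also deposited TPM, which summed to 1000000 in each library over the listed genes, and FPKM, which was proportional to TPM within a library. Per the file headers, the remaining deposited values are normalised read counts, a depth-scaled signal. These equalled the expected count rounded up to a whole number and multiplied by 1.00144, 1 and 0.997 in replicates 1, 2 and 3, for 100% of the values above 0 within a relative tolerance of 1e-06, and they were used only for that check. Each of the 16129 listed genes had a count above 0 in at least 1 library, and no mitochondrially encoded gene was listed. Of the listed gene IDs, 16081 matched the RefSeq annotation of GRCm38.p6 and 15981 of these were protein coding. Coordinates are from that annotation. Of the genes in the fixed lists, 63 were not listed and were not analysed here. They include the constant regions of T cell receptors and immunoglobulins, the cytokines Il9 and Il3 and the dopamine receptors, and no level is given for them.

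TPM was used for all levels, because it allows genes to be compared within a library. A gene was called detected at 1 TPM or more in each of the 3 libraries. Log values are log2(TPM + 1), which understates ratios of low genes. Before the data were examined, 43 gene lists (cell type markers, cytokines, receptors and cellular programs), 11 within-library contrasts and the rule for named genes were fixed. For a contrast, the mean log2 value of the second list or gene was subtracted from that of the first in each library, and the mean and SD of the 3 differences were taken. The exact two-sided sign-flip permutation test over 3 libraries cannot give a p below 0.25, and each of the 11 contrasts gave that value, which Benjamini-Hochberg adjustment over the 11 leaves at 0.25. The position of a list in the profile is the percentile of its median log2 level among 10000 random lists of the same size drawn from the listed genes. This percentile describes these libraries and is not a p-value, since genes are not independent replicates. As an alternative, random lists were drawn from detected genes only. The tested list then kept its undetected members, so a list with such members falls in part by construction. Named genes are the 15 highest by mean TPM without ribosomal protein genes, up to 6 highest members of each list (12 for ILC2 markers, type 2 effectors and cytokine receptors), the genes of the fixed pairs, up to 4 members of a list below 1 TPM in all libraries in alphabetical order, and the 10 genes with the largest range of log2(TPM + 1) among those with a mean of at least 10 TPM. Genes named outside this rule are marked as such. 1 of the contrasts and some genes that the rule names are not reported here.

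The spread between libraries was described by the median SD of log2(TPM + 1), by correlations across genes, by chi-square statistics of rounded expected counts over genes with at least 20 counts in a pair of libraries, and by the common biological coefficient of variation from edgeR 4.0.16 with an intercept only. The programs were tested on simulated data. With 100 genes raised 3-fold in 1 library, 100% were found by the range rule. With 100 genes raised 1.5-fold, and among 8062 genes left alone, 0% were. The rule requires a range of at least 1 on the log2 scale, which 3-fold exceeds and 1.5-fold does not reach. This therefore checks the code and not the sensitivity near that limit. A coefficient of variation of 0.03, simulated without changed genes, was recovered as 0.03 over 11686 genes. Before edgeR was run, expected counts were rounded to whole numbers. Alternatives were a pseudocount of 0.1, detection levels of 0.5 and 5, FPKM or depth-scaled expected counts (CPM) in place of TPM, scaling without ribosomal protein genes, medians in place of means, median-of-ratios scaling, as in DESeq2, and leaving out each library in turn. Sequence sharing between genes was measured as the percentage of a gene's 50-base words, over its GENCODE M21 transcripts, that also occur in a transcript of another listed gene. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3.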

Results

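RNA sequencing profiled ILC2s sorted from the lungs of wild-type mice that had received IL-33, an epithelial alarmin that activates these cells. The profile consisted of 3 libraries of 1 group, with 19948056, 19883728 and 19976129 estimated reads in replicates 1, 2 and 3. At this depth 10852 of 16129 listed genes reached 1 TPM in all 3 libraries, 1658 had a mean of at least 100 TPM and 136 of at least 1000 TPM. Values below are the mean TPM ± SD (n = 3 libraries) unless stated otherwise. The design holds no untreated cells, so the comparisons made are between genes and gene groups within the same libraries.

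The highest transcripts encoded translation factors, cytoskeletal proteins and class I antigen presentation proteins. Without ribosomal protein genes, the leading gene was Eef1a1 (translation elongation, 22674 ± 362), followed by Tmsb4x (an actin-binding peptide, 11233 ± 394), Tpt1 (9536 ± 203) and B2m (the class I light chain, 7012 ± 248). The class I heavy chain genes H2-K1 and H2-D1 stood at 5621 ± 57.5 and 4489 ± 111. These class I genes, and Actb with Actg1, are close relatives among which reads can be split with uncertainty. Eef2, Actg1, Actb, Ubb, Itm2b and Rack1 lay between 5888 ± 176 and 3349 ± 23.1. Rgs1, a regulator of G protein signalling, reached 3206 ± 111, and Fau, which encodes a ribosomal fusion protein, reached 2856 ± 160.4. The remaining member of the top 15 was LOC105244208 (6027 ± 88.9), which RefSeq annotates as the transcribed pseudogene Rps6-ps4. Its reads cannot be separated with certainty from those of Rps6, which was listed at 75.4 ± 4.33 and is named here after its value was seen. Ribosomal protein genes took 21.9%, 22.1% and 21.3% of TPM in replicates 1 to 3.

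The first question was whether the sorted cells carried the transcripts of ILC2s and how far those of other cells were present. All 24 ILC2 core markers were detected, 19 of them at a mean of at least 100 TPM. The highest were Arg1 (arginase 1, 2459.7 ± 88.4), Id2 (a transcriptional regulator required by innate lymphoid cells, 1526 ± 41.1), Il1rl1 (the IL-33 receptor ST2, 1064 ± 33.2), Il2rg (795 ± 34.5), Thy1 (781 ± 30.3), Il17rb (the IL-25 receptor subunit, 714 ± 11.0) and Il7r (659 ± 19.7). Ets1, Ptprc, Icos, Cd44 and Klrg1 lay between 555 ± 4.65 and 356 ± 12.8. Gata3, the lineage-defining transcription factor of ILC2s, reached 255.8 ± 4.999. In GRCm38.p6, Il1rl1 (Entrez gene 17082) lies on chromosome 1 from 40404864 to 40465418, Gata3 (14462) on chromosome 2 from 9857078 to 9887953 and Arg1 (11846) on chromosome 10 from 24915207 to 24927470.

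Markers of other cell types lay far lower as a group, with exceptions. Of 139 listed genes in 14 lists of other cell types, 50 were detected and 16 had a mean of at least 20 TPM. The mean log2(TPM + 1) of the ILC2 core list exceeded that of the other-cell genes by 6.58 ± 0.044 (SD, n = 3), which is 95.8-fold on the TPM + 1 scale. The difference had the same direction in 3 of 3 libraries and was far larger than the spread between them, although the exact two-sided sign-flip permutation test gave p = 0.25, the smallest it can give with 3 libraries. Its size depended on the scale, from 5.94 with FPKM to 7.95 with a pseudocount of 0.1. The ILC2 list's median lay at percentile 100 of random lists, while fibroblast and smooth muscle markers lay at 0.14, mast cell and basophil markers at 1.26, NK and ILC1 markers at 1.46, endothelial markers at 1.79 and B cell markers at 2.79. The ILC3 and Th17 list lay at 3.91, the alpha-beta T cell list at 6.95, the macrophage list at 7.16, the epithelial and eosinophil lists at 8.14 and the neutrophil list at 8.71. The alpha-beta list lacked the receptor constant genes Trac, Trbc1 and Trbc2, which were not listed. The highest percentiles were 11.2 for the erythrocyte and platelet list, 14.6 for the gamma-delta T cell list and 33.2 for the dendritic cell list. Each percentile is taken against random lists of the same size, so percentiles of lists of unlike size do not rank their levels. The 3 listed gamma-delta genes had a median of 0.297 TPM, below the 1.705 TPM of the macrophage list. Among T cell genes Cd3g was an exception at 416 ± 8.15, against 7.19 ± 1.57 for Cd3e and 1.86 ± 0.504 for Cd3d, which encode partner chains of the same receptor complex. Cd3e was at 6.09, 6.48 and 8.99 TPM in replicates 1, 2 and 3. Cd3g (12502) lies on chromosome 9 from 44969572 to 44980431. Lef1 and Cd247 stood at 41.2 ± 2.12 and 20.7 ± 1.45. Pecam1, an adhesion molecule listed as an endothelial marker, reached 79.8 ± 2.76, while the next endothelial gene, Egfl7, was at 2.10 ± 0.464. Ccl5, listed with NK cells, stood at 57.0 ± 2.48, and Cd79b, of the B cell receptor complex, at 21.9 ± 1.82, above its partner Cd79a, which had 9 to 18 estimated reads per library. The epithelial list had 8 of 14 genes detected, led by Cdh1 (23.3 ± 1.02), the secretory cell gene Scgb1a1 (15.3 ± 0.98) and the surfactant gene Sftpc (9.40 ± 1.81).

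**Figure D1:**
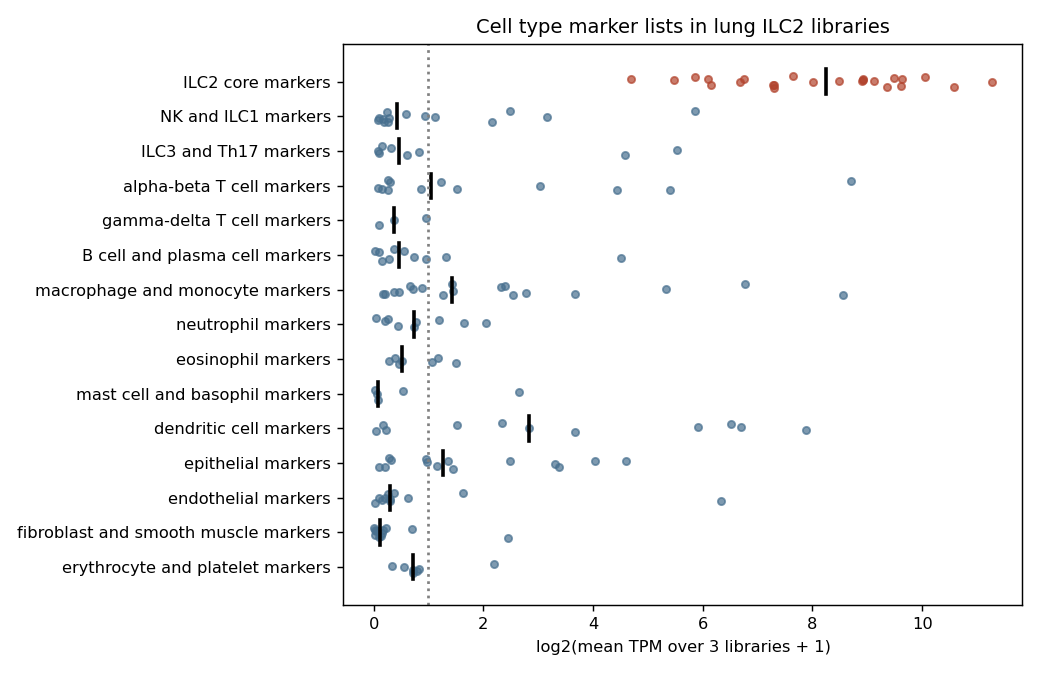
Levels of the listed members of 15 cell type marker lists, 1 point per gene, as log2 of the mean TPM over 3 libraries plus 1 (x axis), with vertical bars at list medians and a dotted line at 1 TPM. The ILC2 core markers all lie above 10 TPM, and single genes such as Cd3g, Pecam1 and Chil3 stand apart within lists whose medians are below 2 TPM.

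Macrophage and class II genes were further exceptions, beside 2 genes of the ILC3 and Th17 list with a mean of at least 10 TPM. The macrophage and monocyte list had 11 of 18 genes detected, with Chil3, a chitinase-like protein of alternatively activated macrophages, at 375 ± 74.7, the chemokine receptor Ccr2 at 108 ± 1.74, the lysozyme gene Lyz2 at 39.1 ± 6.98, Ear2 at 11.7 ± 2.44, C1qb at 5.83 ± 1.21 and Cd68 at 4.81 ± 1.02. Of the 50-base words of Chil3, Ear2 and Lyz2, 16.9%, 23.6% and 15.4% also occur in another listed gene, so their levels are less certain. Chil3 was 1.39 times as high in replicate 3 as in the mean of replicates 1 and 2. For the 9 other macrophage genes of at least 1 TPM that are in no other list, the median of this ratio was 1.40, and 8 of the 9 were highest in replicate 3. In the dendritic cell list, the class II genes Cd74 (234 ± 9.81), H2-Aa (103 ± 0.505), H2-Ab1 (90.4 ± 1.31) and H2-Eb1 (59.0 ± 3.13) led. The next members were Xcr1 (11.7 ± 1.33) and Ccr7 (6.15 ± 0.639), and Clec9a, Flt3 and Siglech were each below 1 TPM in all libraries. The neutrophil list (3 of 9 detected), the eosinophil list (2 of 7) and the erythrocyte and platelet list (1 of 7) had no member above 3.56 ± 0.517, the value of the haemoglobin gene Hba-a1. Of 3 listed gamma-delta T cell genes, 0 were detected, with Cd163l1 near the detection level at 1.04, 0.8 and 0.98 TPM in replicates 1, 2 and 3. The receptor genes Trdc, Trgc1, Trgc2 and Trgc4 were not listed, so this does not show that such cells were absent.

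Lineage-defining transcription factors were compared next. Gata3 exceeded Tbx21, which encodes T-bet of ILC1s (3.46 ± 0.42), by 5.85 ± 0.127 on the log2(TPM + 1) scale (57.8-fold), in 3 of 3 libraries. Of 8 ILC3 and Th17 genes, 2 were detected, both at a mean of at least 10 TPM and 1 of them Il17a. In the same list Ccr6 (0.52 ± 0.183), Cd4 (0.0533 ± 0.0208), Il1r1 (0.247 ± 0.0569) and Il22 (0.0667 ± 0.0577) were below 1 TPM in all libraries. Of 30 transcription factors of innate lymphoid cells, 27 were detected, all of these at a mean of at least 10 TPM. Id2, Nfkb1 (677 ± 17.6), Rbpj (673 ± 22.2), Bhlhe40 (561 ± 21.1), Ets1 and Ikzf3 (296 ± 14.1) were the highest. The 3 below 1 TPM were Bach2 (0.76 ± 0.104), Bhlhe41 (0.263 ± 0.0503) and Zbtb16 (PLZF of innate lymphoid progenitors, 0.187 ± 0.0757).

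The effector profile was dominated by Il13. Il13, a cytokine that drives mucus production and alternative macrophage activation, stood at 972 ± 52.9 and exceeded Il5, the eosinophil growth factor (208 ± 7.02), by 2.22 ± 0.032 on the log2(TPM + 1) scale (4.65-fold). Il5 in turn exceeded Il4 (7.28 ± 2.10) by 4.69 ± 0.372. These 3 genes lie together on chromosome 11, Il4 from 53612460 to 53618665, Il13 from 53631323 to 53634702 and Il5 from 53720794 to 53725103. All 12 listed type 2 effector genes were detected, and their median lay at percentile 97.6 of random lists from listed genes, or 83.1 of lists from detected genes. They included Areg (a growth factor of epithelial repair, 156 ± 10.7), Calca (the precursor of calcitonin gene-related peptide, 85.3 ± 3.89), Il6 (66.5 ± 1.53), Penk (the enkephalin precursor, 52.9 ± 3.54), Retnla (34.7 ± 1.83), Ccl1 (33.8 ± 2.14), Csf2 (16.8 ± 2.25), Il10 (9.48 ± 0.996) and Ccl17 (3.47 ± 1.28).

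Cytokines of the other effector classes were lower but not all below detection. The type 2 cytokines exceeded the type 1 cytokines by 4.43 ± 0.116 and the type 17 cytokines by 5.01 ± 0.113 in mean log2(TPM + 1), in 3 of 3 libraries. Il5 exceeded Ifng (2.79 ± 0.307) by 5.79 ± 0.103. Tnf (51.6 ± 3.55), Lta (14.8 ± 0.598) and Il2 (2.83 ± 0.271) were the other detected type 1 members. Il17a, on chromosome 1 from 20730905 to 20734496, reached 23.0 ± 1.40 and lay 5.34 ± 0.135 below Il13 on that scale, while Il21 stood at 1.84 ± 0.0764 and Il17f at 0.767 ± 0.22. Counting unlisted members as 0, an alternative chosen after seeing the data, lowered the 2 list contrasts to 3.36 and 3.94, since the type 2 list contains Il9. Of 17 chemokines 13 were detected, led by Ccl24 (eotaxin 2, an eosinophil attractant, 123 ± 9.06), Ccl5, Ccl1, Cxcl2 (30.0 ± 1.82), Ccl6 (24.5 ± 3.71) and Cxcl3 (23.9 ± 3.35). Ccl6 was 1.25 times as high in replicate 3 as in the other libraries and Ccl24 was 1.06 times as high, beside 1.39 for the macrophage gene Chil3. The cytotoxic granule list had 5 of 8 genes detected, headed by Srgn (1558 ± 26.6) and Ctsw (810.0 ± 11.2), while Nkg7 was at 26.6 ± 3.23 and Gzma at 4.62 ± 0.963.

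**Figure D2:**
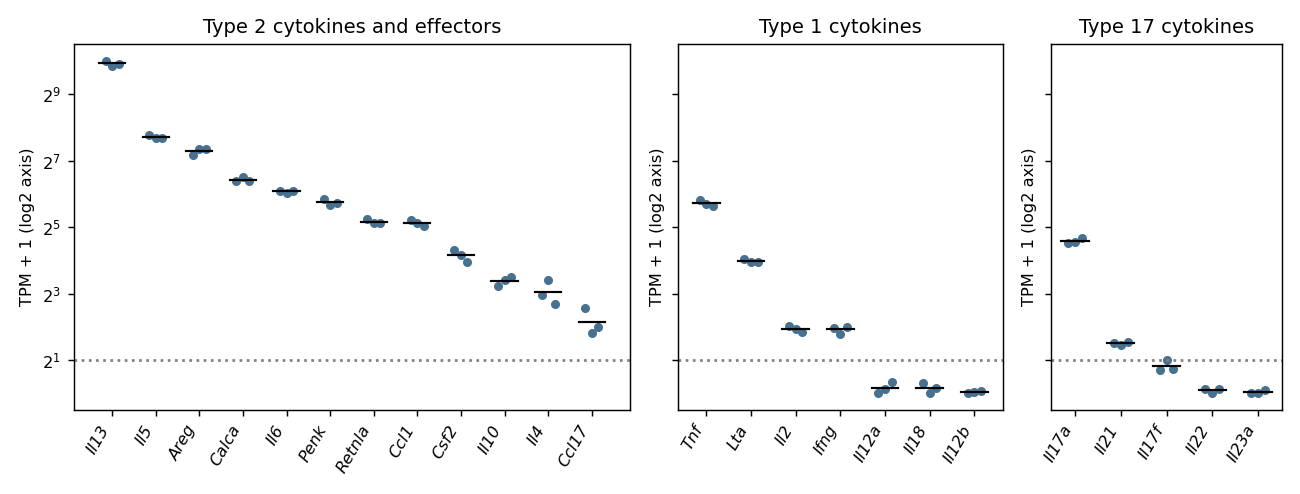
TPM plus 1 on a log2 axis for the listed cytokine and effector genes of 3 classes, with 1 point per library, a bar at the mean and a dotted line at 1 TPM. Il13 stands highest, and within the type 1 and type 17 classes Tnf and Il17a lie above the other members.

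Receptors for alarmins, cytokines, lipids, neurotransmitters and hormones were then examined, 208 listed genes in all, of which 128 were detected. The receptors of the 3 epithelial alarmins were all present. Il1rl1 exceeded Il17rb by 0.57 ± 0.024 (1.49-fold) and Crlf2, the receptor subunit for TSLP (107 ± 4.05), by 3.31 ± 0.042 (9.9-fold) on the log2(TPM + 1) scale, in 3 of 3 libraries. Of 34 cytokine receptor genes 27 were detected. After the alarmin and common gamma chain receptors, the highest were the decoy receptor gene Il1r2 (559 ± 8.72), Il2rb (363 ± 5.22), Tgfbr2 (319.8 ± 9.19), Ifngr1 (231 ± 0.955), Il9r (218 ± 4.33), Il27ra (212 ± 7.16), Il18rap (167 ± 5.31) and Il10ra (114 ± 5.35). Csf2rb, Il13ra1, Il1r1 and Il23r were below 1 TPM in all libraries, the last at 0.113 ± 0.0666.

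Costimulatory and inhibitory receptors and the list of chemokine receptors and integrins both had medians at percentile 99.99 of random lists. Of 20 costimulatory and inhibitory genes 19 were detected, led by the inhibitory receptor Pdcd1 (PD-1, 493 ± 8.32), Icos (484 ± 7.94), Ctla4 (363 ± 28.5), Klrg1, the activation and retention marker Cd69 (284 ± 2.45) and Tigit (229 ± 15.0). Among TNF superfamily genes 16 of 18 were detected, with Ltb (921 ± 14.7), Tnfsf14 (191 ± 8.82), Tnfrsf18 (GITR, 157 ± 3.74), Tnfsf10 (147 ± 5.14), Tnfrsf1b (108 ± 4.59) and Tnfrsf25 (DR3, 95.5 ± 3.83) highest. The median of that list lay at percentile 96.2, or at 64.4 against lists from detected genes, which hold no undetected member. Of 25 chemokine receptors and integrins 20 were detected. Cxcr6 (1317 ± 31.7), Itgb7 (1021 ± 38.5), Itgae (CD103, 978 ± 22.9) and Ccr8 (757 ± 19.8) headed this list, followed by Itgb2 (534 ± 5.36) and Itgal (479 ± 11.7). Ccr10, Ccr6, Cxcr3 and Cxcr5 were each below 1 TPM in all libraries.

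Lipid mediator receptors were widely detected (13 of 16), with a median at percentile 94.95 of random lists from listed genes. The percentile was 63.8 against lists from detected genes, which hold no undetected member. Ltb4r1, the leukotriene B4 receptor, was highest at 372 ± 8.53, followed by the prostaglandin E2 receptor gene Ptger4 (114 ± 2.14), Lpar6 (109 ± 3.37), the cysteinyl leukotriene receptor gene Cysltr2 (95.2 ± 5.69), the prostacyclin receptor gene Ptgir (93.3 ± 4.19) and S1pr4 (80.1 ± 3.50). Both prostaglandin D2 receptor genes were close to 0, with Ptgdr at 0.17 ± 0.0889 and Ptgdr2, which encodes CRTH2, at 0.04 ± 0.0346.

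Receptors for neural signals were mostly low, with a small set detected. Of 17 listed neuropeptide receptor genes 5 were detected, namely Ramp1 (218 ± 2.68), Vipr2 (a receptor for vasoactive intestinal peptide, 152 ± 3.55), Ramp3 (45.1 ± 5.16), Nmur1 (the neuromedin U receptor, 43.4 ± 3.32) and Calcrl (39.96 ± 1.73). Ramp1 and Calcrl together encode the receptor for calcitonin gene-related peptide. Vipr1 was at 1.02 ± 0.291 and passed 1 TPM in 1 library. Of 7 adrenergic receptors 2 were detected, with Adra1b at 3.64 ± 0.202. Among 14 cholinergic genes Chrnb1 (5.65 ± 0.514) and Ache (1.40 ± 0.28) were detected. Of 9 serotonin genes the detected ones were Tph1, the first enzyme of serotonin synthesis (9.84 ± 0.916), and the receptor gene Htr2a (1.38 ± 0.401). Of 15 GABA and glutamate receptor genes 2 were detected, Grin2d (66.5 ± 2.71) and Gabbr1 (38.7 ± 2.20). The medians of the adrenergic, serotonin, cholinergic, and GABA and glutamate lists lay at percentiles 0.63, 0.5, 0.22 and 0 of random lists. Purine and histamine receptors had 9 of 16 genes detected, led by P2ry10 (188 ± 2.92), P2rx7 (43.0 ± 2.16), P2rx4 (32.9 ± 1.09), P2ry1 (29.6 ± 0.559) and Adora2a (29.5 ± 3.56). Nuclear receptors had 13 of 19 detected, among them Nr4a1 (542 ± 22.8), Pparg (189 ± 4.99), the glucocorticoid receptor gene Nr3c1 (185 ± 5.02), Nr1h2 (91.7 ± 1.197), Rara (71.5 ± 1.39) and Rarg (53.5 ± 3.28), while Esr1, Esr2, Nr3c2 and Pgr were each below 1 TPM in all libraries.

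**Figure D3:**
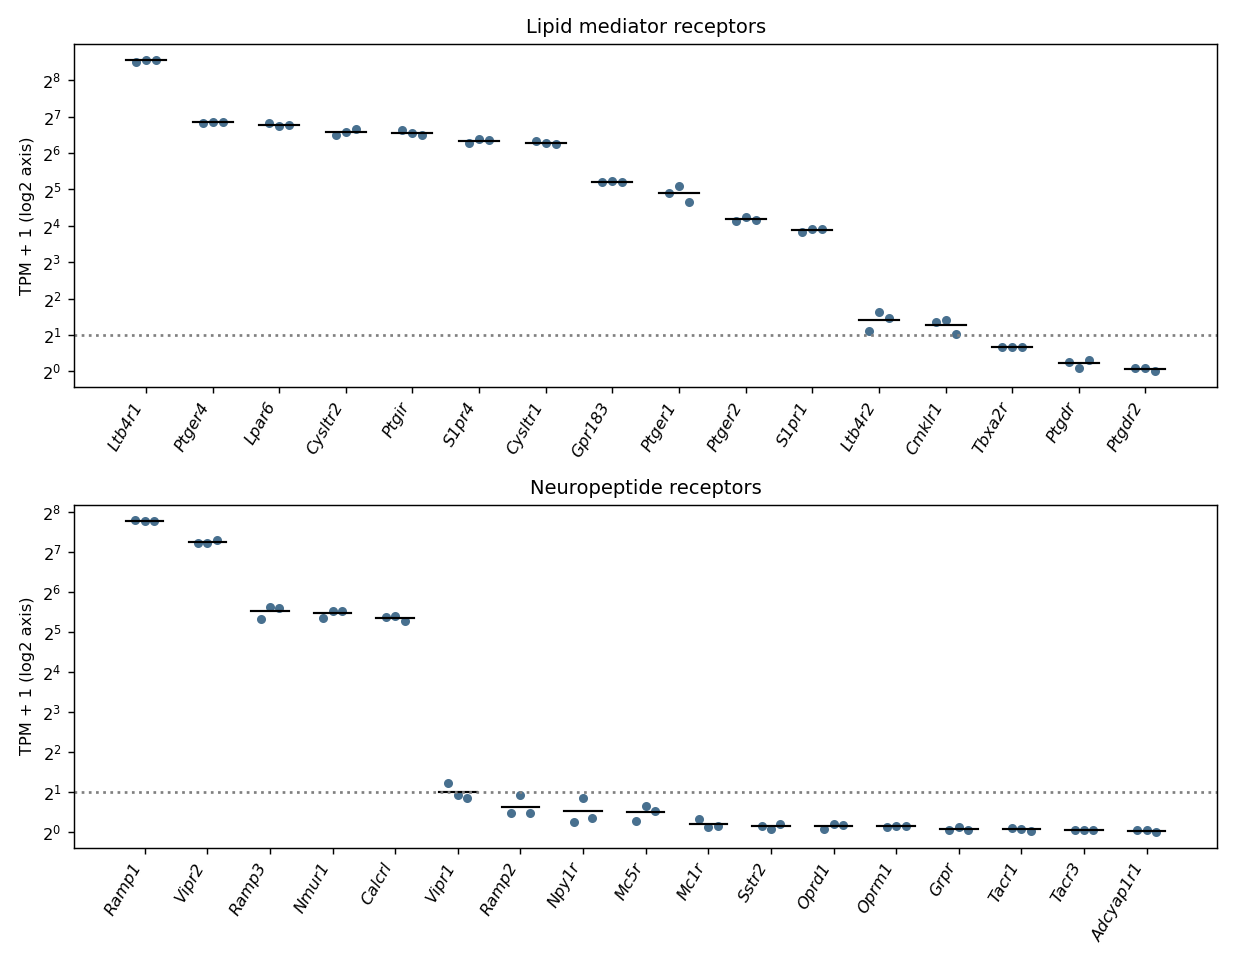
TPM plus 1 on a log2 axis for lipid mediator receptors (upper panel) and for neuropeptide receptors (lower panel), with 1 point per library, a bar at the mean and a dotted line at 1 TPM. Ltb4r1, Ramp1 and Vipr2 stand highest, and Ptgdr2 and most neuropeptide receptors lie near 0 TPM in every library.

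Programs of proliferation, metabolism and acute activation were detected nearly in full. All 26 cell cycle genes were detected at a mean of at least 10 TPM, with Tubb5 (793 ± 52.6), Stmn1 (443 ± 20.3), the replication clamp gene Pcna (419.9 ± 16.4), Mcm6 (214 ± 8.45), Top2a (203 ± 3.09) and Mcm3 (155 ± 3.71) highest. All 17 glycolysis genes were detected, led by Gapdh (2480.4 ± 33.8), Ldha (1342 ± 50.7), Aldoa (1169 ± 50.9), Pkm (884 ± 18.9), Eno1 (599 ± 24.9) and Gpi1 (565 ± 20.7). All 23 nuclear-encoded genes of oxidative phosphorylation were detected, led by Cox4i1 (1080.2 ± 55.9) and Atp5b (913 ± 23.9). Fatty acid genes (17 of 18 detected) were headed by Hadha (218 ± 6.58), Plin2 (183 ± 6.49), Hadhb (175 ± 7.05), Acadl (147 ± 3.17) and Cpt1a (134 ± 3.29). After Arg1, the amino acid list (17 of 18) was led by Slc1a5 (162 ± 3.36), Odc1 (158 ± 6.08), Slc3a2 (137 ± 1.54) and Psat1 (132 ± 3.65), and Arg2 was the member below 1 TPM in all libraries at 0.13 ± 0.0866. Immediate early genes, which tissue dissociation is also known to induce, were detected in full (18 of 18), with Junb (1770.5 ± 80.0), Nr4a1, Fos (410.4 ± 4.19), Jund (352 ± 5.89), Btg2 (255.8 ± 9.61) and Dusp1 (244 ± 12.1) highest. The medians of these 6 lists lay at percentiles of 99.96 to 100 of random lists, as did the 14 housekeeping genes at 100. The interferon response list (12 of 15 detected) lay at 44.4, with Bst2 at 68.7 ± 2.37. Its percentile was 1.15 against lists from detected genes, but those lists hold no undetected member while this list does.

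The libraries differed little from each other. The median SD of log2(TPM + 1) over detected genes was 0.061, against 0.0404 in a simulation with counting error alone. Across detected genes, which are not independent replicates, Pearson's r between pairs of libraries was 0.997 to 0.998, and Spearman's rho was 0.998 for each pair. The chi-square statistic per degree of freedom was 3.47 for replicates 1 and 2, 3.25 for replicates 1 and 3 and 2.48 for replicates 2 and 3, where counting error alone gives 1. The median per gene was 0.970, 0.922 and 0.761 in the same order, where counting error alone gives 0.455. The 100 genes with the largest values gave 23.8% to 26.9% of the statistic. The libraries were counted as 3 samples because their labels list them as such, and this statistic does not tell separate animals from repeat libraries of 1 RNA pool. The common biological coefficient of variation from edgeR was 0.034. Of 8262 genes with a mean of at least 10 TPM, 2 had a range of at least 1 on the log2 scale. These were 1700047I17Rik2, at 0.28, 26.1 and 8.69 TPM in replicates 1 to 3, and Zfp967, at 13.2, 14.5 and 2.88 TPM. Leaving out replicate 1, 2 or 3 left 1, 0 or 1 such genes, and the lower level of 1 TPM gave 44. The next by range were Fam177a, Smim27, H4c9, Rpl23, Spp1, Gm2004, Rpl37rt and Mmp12, with ranges of 0.87 to 0.71.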

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

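The 3 list contrasts kept their direction under every alternative run, and their size depended on the scale. FPKM and rescaling without ribosomal protein genes multiply all values of a library by a single factor. They therefore change only the weight of the pseudocount and are not separate checks from the pseudocount of 0.1. With a pseudocount of 0.1 they were 7.95 (ILC2 core minus other-cell markers), 5.66 (type 2 minus type 1 cytokines) and 6.45 (type 2 minus type 17 cytokines) on the log2 scale. In the same order they were 7.62, 5.43 and 6.48 with medians over members, 5.94, 3.94 and 4.41 with FPKM, 6.98, 3.82 and 4.22 with CPM, 6.78, 4.59 and 5.198 when TPM was rescaled without ribosomal protein genes, and 6.79, 3.36 and 3.94 when members not listed were counted as 0, an alternative chosen after seeing the data. Of the 8 gene pairs, a pseudocount of 0.1 moved Gata3 minus Tbx21 to 6.18 and Il5 minus Ifng to 6.17. Leaving out each library in turn gave 1, 0 and 1 genes with a range of at least 1 without replicates 1, 2 and 3, because the mean of 1700047I17Rik2 or Zfp967 then fell below 10 TPM or the divergent library was absent. With a level of 1 TPM the count was 44. The other 79 alternative values of these and the remaining summary results stayed within 1 SD, or within 1.5 times for counts. Of the 42 list percentiles, 2 fell below 95 when random lists were drawn from detected genes only, namely type 2 cytokines and effectors (83.1) and TNF superfamily genes (64.4), and lipid mediator receptors passed 95 without replicate 3 (95.7). Against detected genes, lipid mediator receptors also fell to 63.8, nuclear receptors to 14.4, type 1 cytokines to 0.08, dendritic cell markers to 0.44, cytotoxic granule genes to 0.21 and interferon response genes to 1.15. These lists kept undetected members, which the random lists could not hold, so part of each fall is built in. The values do not place the detected members among detected genes. The planned filter on genes above 0 removed no gene and tested nothing. No paired analysis was possible because the libraries form a single group. Depth limits low genes: Il4 rested on 28 to 49 estimated reads per library.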

Other observations

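The tests on Arg1 and on T cells were chosen after the results were seen, as was the naming of genes outside the rule. The tests on macrophage transcripts and on genes overlapping Il17a and Cd3g addressed patterns already seen in these data. Below the 15 highest genes, several high genes were in no fixed list. Laptm5, a lysosomal protein of blood cells, stood at 2158 ± 57.2 TPM (SD, n = 3), the surface antigen gene Cd52 at 2097 ± 49.9, the fibrinogen-like protein gene Fgl2 at 1918 ± 72.9, the calcium-binding protein gene S100a4 at 1880.5 ± 198, Coro1a at 1813 ± 58.0, Ly6e at 1417 ± 69.3 and the mitochondrial carrier gene Ucp2 at 1374 ± 55.4. Calca and both genes of its receptor, Ramp1 and Calcrl, were detected in the same libraries.

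Of 9 macrophage transcripts tested, 8 were highest in replicate 3, while Arg1, Retnla, Il13 and Il5 were not. The median ratio of replicate 3 to the mean of replicates 1 and 2 was 1.40 over 9 macrophage genes. It ranged from 0.756 for Fabp4, which had 7 to 11 reads per library, to 1.59 for Csf1r. The ratio was 1.39 for Chil3, 1.70 for Spp1, 1.38 for Mmp12 and 1.43 for Ccl9. Replicate 3 and the direction were chosen from Chil3, Spp1 and Mmp12, so their own ratios add no support. The shift was neither shared by the whole macrophage list nor confined to it. Ccr2 was at 109.55, 108.18 and 106.1 TPM in replicates 1, 2 and 3. Of other lists, Cd3e (6.09, 6.48 and 8.99) and Gzma (3.86, 4.29 and 5.7) were highest in replicate 3, while Hba-a1 (3.46, 4.12 and 3.1) was not. Other lists were not tested as sets. A candidate explanation is macrophage RNA or cells in an amount that differs between libraries, but these values do not single out macrophages. The cells were sorted with gates not given in the sources used here. For Arg1 the ratio was 0.973, and Retnla (0.952), Il13 (0.975) and Ccl24 (1.06) also lacked the shift. Arg1 thus did not follow the 8 macrophage genes that were highest in replicate 3. Because Ccr2, of the macrophage list, lacked the shift too, this does not decide whether macrophage RNA was the main source of Arg1. Whether any macrophage RNA came from whole cells or from free RNA was not tested. The design gives no group from which a biological explanation could be tested.

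Cd3g was measured at a level that its usual partner genes did not share, and Il17a stood well above Il17f and Il22. The higher of Cd3e and Cd3d was at most 2.19% of Cd3g, which argues against T cells as the source of Cd3g. No test here bears on which cells hold Il17a. The number of annotated genes listed at 1 TPM or more that overlap Il17a or Cd3g in GRCm38.p6 was 0 (reads of an overlapping gene), and 0% of their 50-base words occurred in another listed gene. That the sorted ILC2s themselves hold these transcripts, in all cells or in a subset, may be asked of single cells, and no biological explanation was tested here.

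Of the 10 genes that differed most between libraries, 6 shared at least 28.9% of their sequence words with other listed genes. The mean share of 50-base words found in another listed gene was 45.1% for the 10 genes of largest range, at percentile 100 of 10000 random lists of similar level, whose median was 0.405%. For these 6 genes a candidate explanation is that reads shared with other genes were divided differently in each library. Summed counts were checked only for the pairs of 1700047I17Rik2 and of Zfp967, and not for H4c9, Gm2004 or Rpl37rt. All words of 1700047I17Rik2 occur in Fam177a, and the summed counts of the pair were 1994.9, 1879.8 and 1994.8, a range of 0.086 on the log2 scale against 4.40 for 1700047I17Rik2 alone. For Zfp967 and Zfp966 the sums had a range of 0.22 against 2.00. The other 4 shared little, Spp1 0%, Mmp12 0.162%, Rpl23 0.988% and Smim27 4.09%, and their ranges stay unexplained. Spp1 and Mmp12 were highest in replicate 3, as most macrophage genes tested were. That replicate and direction were chosen from these 2 genes and Chil3, so the likeness accounts for neither range. Mmp12 had a replicate 3 ratio of 1.38 but also differed between replicates 1 and 2 (10.5 and 15.3 TPM, with 17.9 in replicate 3). The pseudogene LOC105244208 at 6027 ± 88.9 TPM beside Rps6 at 75.4 ± 4.33 shows the same ambiguity at a high level, since 43.8% of the words of Rps6 occur in it.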
